A study of Atriplex lentiformis with 8 samples.

How the data were processed

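RNA from leaves of Atriplex lentiformis was sequenced in 8 libraries, 4 from plants grown at 23 °C and 4 from plants grown at 43 °C, which the series' design text calls biological replicates. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie2 were used, with no role given. Libraries followed standard Illumina protocols from total RNA, per the labels' protocols, and whether RNA was selected by its poly(A) tail is not given in the sources used here.

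The single table analysed had 46492 assembled transcripts, from 201 to 16987 bases long. Per the file headers, its expression columns are FPKM, fragment counts scaled for transcript length and sequencing depth, at each temperature. All FPKM values were multiples of 0.0025 (within 1e-6), as means of 4 values with 2 decimals would be, so they were taken as the authors' means. Per the file headers, the table also gives the authors' log2 fold change of 43 °C against 23 °C, a p-value, an FDR and the best BLASTx match in the TAIR10 Arabidopsis proteins. The test behind the authors' deposited p-value, the counting tool, the assembler and the normalization are not given in the sources used here. The FDR column equalled a Benjamini-Hochberg adjustment of the p-values over all transcripts to within 3.2e-07. The authors' log2 column differed from the log2 ratio of the mean FPKM values by a median of -0.0085 where both exceeded 5. Multiplied by transcript length in kilobases, the FPKM values summed to 1084419 at 23 °C and 909555 at 43 °C, and the reason for the difference is unknown. Matches had E values of at most 1e-06. No transcript was listed at 0 at both temperatures and every transcript listed at 0 at 1 of them passed, which leaves open a selection of transcripts before deposit; and 655 transcripts had a p of 1.

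Because the table held means and the authors' own comparison, no test between groups was run, although a test on single libraries had been planned. Calls are the authors' adjusted p at a threshold of 0.05, and 25 adjusted p-values were listed as 0. Read depth per library is unknown, so the precision of single values is known only through the authors' p-values. Chamber and temperature coincide, per the labels' protocols. Whether the p-values rest on the spread between replicate plants is not given in the sources used here.

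Before the data were examined, 28 lists of Arabidopsis genes (530 genes) were fixed: 9 of lipid metabolism, and others for epidermal wax and cutin, small heat shock proteins, large chaperones, heat shock factors, the unfolded protein response, antioxidants, abscisic acid response, photosystems, the Calvin cycle, the C4 cycle, photorespiration, starch and sucrose, phenylpropanoids, the clock, senescence, cell division, vascular tissue, guard cells and floral genes. A transcript belonged to a list through its matched locus, which 384 of the genes had, with 807 transcripts. Counts are given per gene, by its most abundant transcript, and over all transcripts. In place of a set test, each list's median log2 change was placed among the medians of 10000 random lists of as many matched transcripts, drawn from the same 20 bins of mean FPKM, and outside the central 95% a list was counted as standing apart. The number passing in a list was also recomputed with p adjusted over the list alone.

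Named genes followed a rule fixed at the same time: the 10 highest and 10 lowest log2 changes among passing matched transcripts in the upper part of abundance (above the median), each by the most abundant transcript of its locus, the glycerolipid genes of the study's subject whatever their result, and from each list up to 2 risen, 2 fallen and 2 not passing. A further condition, that values of the 2 groups do not overlap, could not be applied to means. The 19 further groups, and the genes named from them, were chosen after their values had been seen. The most abundant transcript is described for genes whose transcripts moved apart, since assembled variants and close copies can share reads, and the FPKM of all transcripts of a locus were also summed.

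Alternatives were an adjusted p threshold of 0.01, minimum mean FPKM of 1 or 5, pseudocounts of 0.1, 1 and 5 in place of the deposited log2 values, quantile normalization, median centring, equal length-weighted totals, a size test against a 1.5-fold change, sums per locus, the most abundant transcript per locus, matches with E values of at most 1e-30, and leaving out transcripts listed at 0. Quantile normalization was applied to log2 values of the mean FPKM with a pseudocount of 1, not to the deposited log2 values. For centring, equal totals and the size test, calls were approximated from the standard error that a normal test would need for the authors' p. Data were simulated at the abundances of the 46492 transcripts, with a small share changed and a standard error that was assumed, not taken from the data. There the adjustment recovered 14% of transcripts changed by 1 and 71% of those changed by 3 on the log2 scale, with 4.49% false calls. Since 38.5% passed in the real data, these shares do not give the sensitivity of the authors' calls. A constant shift was put in and taken out by the same normal formula, so the 100% of calls recovered checks the code only. In simulated lists of 20 drawn from the 30203 matched transcripts, 2.5% of unchanged lists fell outside the central range and 88% of lists raised by 1 SD lay above it. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.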

Results

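Leaf RNA of Atriplex lentiformis (quailbush), a salt-tolerant shrub with C4 photosynthesis, was sequenced in 8 libraries. The design gave 4 biological replicates at each of 2 growth temperatures. Plants of the cool group stood in a chamber at 23 °C by day and 18 °C by night, and plants of the hot group in another chamber at 43 °C by day and 30 °C by night. Both groups had a 16-hour photoperiod, and the labels give 8 weeks for each. The labels also assign a 16:3 lipid phenotype to the cool leaves and an 18:3 lipid phenotype to the hot leaves. By background knowledge, 16:3 plants assemble part of their chloroplast glycerolipids inside the plastid and so carry a 16-carbon fatty acid with 3 unsaturated bonds, whereas 18:3 plants take the backbones of these lipids from the endoplasmic reticulum. The comparison of the 2 temperatures asks which leaf transcripts, those of the lipid pathways among them, differed between these growth conditions.

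The data were 46492 assembled transcripts, with the authors' mean FPKM at each temperature and the authors' log2 fold change, p-value and adjusted p. No values of single libraries were analysed here, so every FPKM below is an authors' mean without an SD, and read depth is unknown. A transcript is said to have risen or fallen where its adjusted p in the authors' deposited table was below 0.05. Of the transcripts, 30203 (65.0%) had a best match to an Arabidopsis protein, and these matches covered 12468 loci. Genes are named after that match, which does not show orthology, and values are those of the most abundant matched transcript unless stated. Other transcripts of a gene did not always agree: of the 142 genes named in the text that passed, 9 had another transcript, with at least 25% of the abundance of the main one, that changed the other way, and 18 had one that did not pass. That threshold was chosen after the values had been seen.

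Growth at 43 °C went with higher transcripts of small heat shock proteins, chaperones, endoplasmic reticulum stress genes and cell division genes. Transcripts of nuclear photosystem genes, the C4 cycle, photorespiration and starch metabolism were lower, as was the most abundant transcript of ATS1, the acyltransferase that opens the plastid lipid pathway. HSP22.0, a small heat shock protein, went from a mean of 1.46 to 164 FPKM, HSP90.1 from 30.7 to 448 FPKM, ATS1 from 41.1 to 12.2 FPKM and the most abundant transcript of the light-harvesting protein gene LHCB1.3 from 5298 to 824 FPKM. In the authors' deposited table, 9618 transcripts were higher and 8291 were lower at 43 °C, together 17909 (38.5%) of all transcripts. A change of at least 2-fold was listed for 7056 of the higher and 4914 of the lower transcripts. All 867 transcripts listed at 0 at 23 °C were among the higher and all 361 listed at 0 at 43 °C among the lower, and no fold is given for them. How transcripts were chosen for the table is not given in the sources used here, so these totals and shares describe the deposited transcripts only.

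Direction depended on abundance. Among the 10% of transcripts with the highest mean FPKM 1233 rose and 2262 fell, with a median log2 change of -0.21 in the authors' deposited table, whereas among the 10% with the lowest 945 rose and 358 fell. The smallest log2 change that passed was 0.16 among the most abundant of these and 1.63 among the least abundant, so changes of rare transcripts had to be large to be called. The FPKM columns differed in their totals: multiplied by transcript length in kilobases they summed to 1084419 at 23 °C and 909555 at 43 °C. Scaling both to one total would add 0.25 to every log2 fold change. That exceeds the size of the median of -0.21 among the most abundant transcripts, so that median would turn positive. The contrast between abundant and rare transcripts would remain. With equal totals the split would be an estimated 12953 higher and 5982 lower transcripts (68.4% higher, against 53.7% as deposited). Below, a direction that this or another scaling turns is named beside the gene.

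The 10 transcripts that rose most among the more abundant matched ones included CHI-B, a basic chitinase, which was listed at 0 at 23 °C and at 77.7 FPKM at 43 °C. Also listed at 0 at 23 °C were KNAT1, a homeobox regulator of shoot meristems (3.27 FPKM at 43 °C), the protein kinase CONNEXIN 32 (6.67 FPKM, while another transcript fell from 1.4425 to 0.28 FPKM), a pectin lyase-like protein (AT5G47500, 3.36 FPKM), a B3 transcription factor (AT5G32460, 3.60 FPKM) and a mitovirus-type RNA polymerase (AT2G07749, 3.86 FPKM). The other 4 were an HSP20-like chaperone (AT2G29500, 0.04 to 23.52 FPKM), a reverse transcriptase-related protein (AT3G24255, 0.0075 to 6.55 FPKM), a protein of unknown function (AT1G16810, 0.04 to 14.74 FPKM) and the mitochondrial reading frame ORF107G (0.0375 to 9.19 FPKM). The 10 that fell most began with a pathogenesis-related PR1 family protein (AT4G33720, 280.3 to 0.0625 FPKM). BG3, a beta-1,3-glucanase, fell from 336 to 0.645 FPKM, a basic secretory protein (AT2G15220) from 60.4 to 0.09 FPKM, and a peroxidase (AT3G01190) from 20.2 to 0.005 FPKM. Also among them were 2 methyltransferases (AT3G21950, 47.6 to 0.123 FPKM, and AT5G38020, 3.73 FPKM to a listed 0), a CDC48 ATPase (AT5G03340, 5.21 to 0.005 FPKM), and SUS6, VSR6 and PPa5, which were listed at 0 at 43 °C from 5.90, 5.13 and 3.82 FPKM. Over all their transcripts, SUS6 summed to 7.53 FPKM at 23 °C and 4.35 FPKM at 43 °C, and VSR6 to 7.455 and 1.83 FPKM. The 10 largest rises thus came from 23 °C values of at most 0.04 FPKM for the single transcripts. Summed over all transcripts of the locus, some of these genes had more at 23 °C. CONNEXIN 32 summed to 6.44 FPKM at 23 °C and 13.8 FPKM at 43 °C, and AT3G24255 to 8.79 and 17.3 FPKM. AT1G16810 summed to 2.93 and 17.5 FPKM, and CHI-B to 0.4425 and 77.9 FPKM. In a further ranking, chosen after the values had been seen and limited to transcripts with at least 1 FPKM at both temperatures, a DUF538 protein (AT1G61667) rose most, from 3.45 to 472 FPKM. Another transcript of it fell from 144 to 124 FPKM, a log2 change of -0.23 that equal totals turned positive. HSP22.0, HSP21, the mitochondrial reading frame ORF107A (4.53 to 221 FPKM), a major facilitator family transporter (AT5G18840, 6.955 to 298 FPKM) and the metallothionein MT3 (6.97 to 266 FPKM) were also among its 10 highest. An aspartyl protease (AT1G64830) fell most, from 105 to 1.24 FPKM.

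Within the plastid pathway of glycerolipid assembly, ATS1 fell by 1.76 on the log2 scale (adjusted p = 6.09e-97) in the authors' deposited table. A second ATS1 transcript did not pass at 12.3 and 14.4 FPKM, and the 3 transcripts of the gene summed to 55.6 FPKM at 23 °C and 28.3 FPKM at 43 °C. ATS2, the next acyltransferase of that pathway, fell from 6.91 to 4.55 FPKM, and CDS4, a plastid CDP-diacylglycerol synthase, from 14.1 to 6.32 FPKM. GLY1, which makes glycerol-3-phosphate for the plastid, did not pass at 3.45 and 2.96 FPKM, nor did PGP1 (16.7 and 18.4 FPKM) or LPPgamma (16.1 and 17.3 FPKM). Another GLY1 transcript rose from 0.42 to 2.62 FPKM, and the 9 transcripts of GLY1 summed to 8.81 FPKM at 23 °C and 11.15 FPKM at 43 °C. Of the 9 matched genes on this list 3 fell, none rose and 6 did not pass. Over its 25 transcripts, 1 rose and 3 fell, and 3 passed when adjusted over the list alone. Among galactolipid synthases, MGD1 fell from 23.2 to 16.4 FPKM, DGD1 from 53.1 to 30.2 FPKM and DGD2 from 13.6 to 8.55 FPKM, while MGD2 did not pass at 4.41 and 3.48 FPKM. SQD1, of sulfolipid synthesis, fell from 30.4 to 23.4 FPKM, while SQD2 did not pass at 52.5 and 59.3 FPKM. On the galactolipid and sulfolipid list 5 of 8 genes fell and 3 did not pass. Its 20 transcripts had 4 higher and 6 lower, and 10 passed when adjusted over the list alone. The 4 higher ones all matched SFR2, whose most abundant transcript did not pass at 8.065 and 6.23 FPKM. Another SFR2 transcript rose from 1.205 to 4.365 FPKM, and a further SFR2 transcript fell from 9.125 to 2.85 FPKM. All 11 transcripts of SFR2 summed to 20.8 FPKM at 23 °C and 18.1 FPKM at 43 °C.

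The desaturases moved in both directions. FAD2, the oleate desaturase of the endoplasmic reticulum, rose from 67.8 to 147 FPKM, a log2 change of 1.11 (adjusted p = 9.35e-48) in the authors' deposited table. FAD5, the plastid palmitate desaturase, fell from 120.3 to 62.3 FPKM (log2 change -0.96, adjusted p = 7.54e-25 in the authors' deposited table). FAD6, the plastid oleate desaturase, fell from 165 to 143 FPKM and the stearoyl desaturase FAB2 from 103 to 90.3 FPKM, but both log2 changes turned positive (0.041 and 0.054) when the totals were made equal. A second stearoyl desaturase, SAD5, rose from 23.0 to 119 FPKM, while its other transcript did not pass at 43.8 and 46.7 FPKM. FAD4, a plastid desaturase, rose from 13.5 to 17.615 FPKM, a call that ended after median centring. FAD7 (5.62 and 3.77 FPKM) and FAD8 (179 and 185 FPKM), which make trienoic fatty acids in the plastid, did not pass. No transcript matched FAD3. Of 8 desaturase genes 3 rose, 3 fell and 2 did not pass; of the 20 transcripts 6 rose and 4 fell, and 10 passed when adjusted over the list alone.

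**Figure D1:**
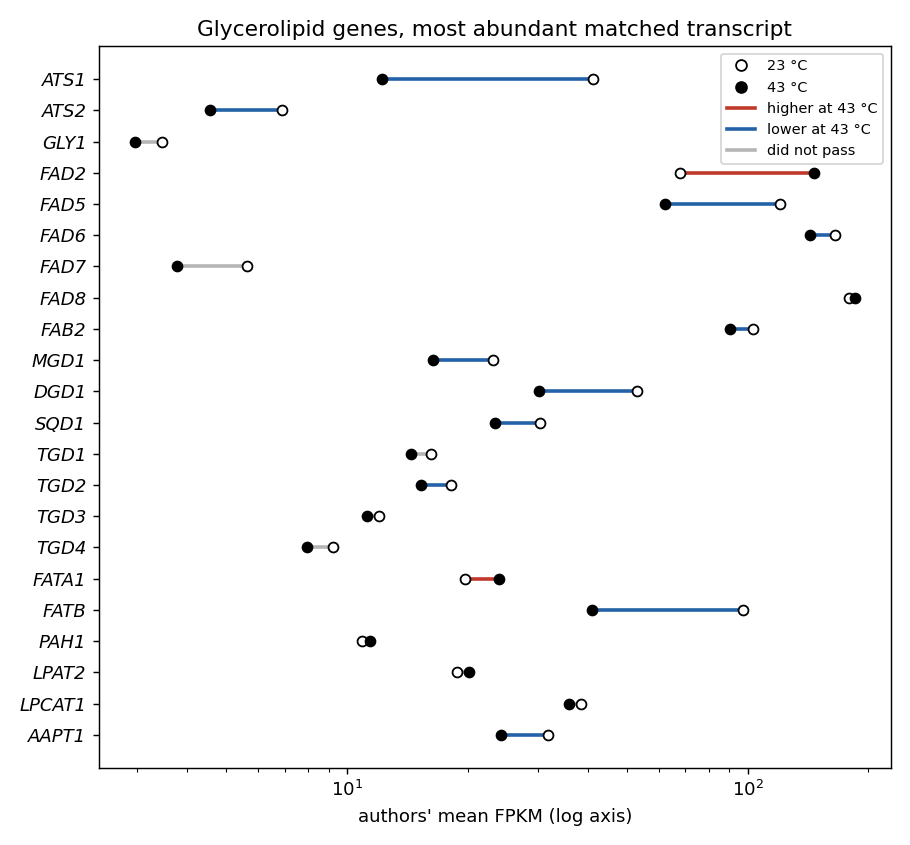
Authors' mean FPKM (log axis) of 22 glycerolipid genes at 23 °C (open circles) and 43 °C (filled circles), each by its most abundant matched transcript, with the line coloured by the authors' call. ATS1 (41.1 to 12.2 FPKM), FATB (97.6 to 41.0 FPKM) and FAD5 (120.3 to 62.3 FPKM) moved left and FAD2 (67.8 to 147 FPKM) moved right.

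Genes of glycerolipid assembly in the endoplasmic reticulum fell or did not pass more often than they rose. The main change was in NMT2 (PMEAMT), a methyltransferase of phosphocholine synthesis, which fell from 3811 to 339 FPKM, and a second NMT2 transcript fell from 263 to 101 FPKM. AAPT1, which joins head groups to diacylglycerol, fell from 31.7 to 24.3 FPKM. LPAT2 (18.8 and 20.2 FPKM), LPCAT1 (38.5 and 35.9 FPKM) and the phosphatidate phosphatase PAH1 (10.9 and 11.4 FPKM) did not pass, while GPDHc1, a glycerol-3-phosphate dehydrogenase, rose from 9.96 to 15.8 FPKM. The inositol lipid synthase PIS1 rose from 5.34 to 12.9 FPKM by its most abundant transcript, but 2 others fell (8.99 to 3.30 FPKM and 6.61 to 2.04 FPKM), and the sum over its transcripts was lower at 43 °C (log2 ratio -0.30). Of 20 genes 3 rose, 10 fell and 7 did not pass, and of 60 transcripts 6 rose and 21 fell (29 passed when adjusted over the list alone). CCT1 had no match. For lipid transfer into the plastid, TGD2 fell from 18.22 to 15.3 FPKM, and TGD1 (16.3 and 14.4 FPKM), TGD3 and TGD4 (9.22 and 7.97 FPKM) did not pass, TGD3 with 11.2 FPKM at 43 °C. The acyl-CoA synthetases LACS4 and LACS9 fell from 49.5 to 28.3 FPKM and from 21.3 to 18.1 FPKM. That list had 3 of 7 genes lower and none higher, and 3 transcripts up and 3 down of 12, with 6 passing when adjusted over the list alone. With equal totals the log2 change of LACS9 was 0.0090, ATS2, SQD1, TGD2 and AAPT1 no longer passed, and PGP1, LPPgamma, SQD2, FAD8, LPAT2 and PAH1 passed as higher.

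In fatty acid synthesis, FATB, the thioesterase that releases palmitate, fell from 97.6 to 41.0 FPKM, and CAC3, a subunit of acetyl-CoA carboxylase, from 48.4 to 26.2 FPKM. FATA1, the thioesterase that releases oleate, rose from 19.7 to 23.9 FPKM (adjusted p = 0.035 in the authors' deposited table), as did the dehydratase HAD2 (15.9 to 25.3 FPKM) and the enoyl reductase MOD1 (36.0 to 48.8 FPKM). KASI did not pass at 36.2 and 35.7 FPKM, and FATA1 no longer passed after median centring (log2 change 0.17). The list had 7 of 20 genes higher and 9 lower, with 9 and 11 of its 34 transcripts and 21 passing when adjusted over the list alone. Among triacylglycerol and lipid droplet genes, PDAT1 rose from 15.0 to 26.6 FPKM, LDAP3 fell from 84.4 to 42.7 FPKM and the lipase SDP1 from 12.3 to 7.30 FPKM, while LDAP1 did not pass at 143 and 136 FPKM. There 1 of 6 genes rose and 2 fell, as did 1 and 2 of 10 transcripts, and 3 passed when adjusted over the list alone. Of 9 genes for phospholipases and diacylglycerol kinases, 1 rose (NPC6, 7.68 to 11.0 FPKM, which no longer passed after median centring) and 5 fell, among them the kinases DGK5 (19.1 to 7.16 FPKM) and DGK1 (9.90 to 5.75 FPKM). The other NPC6 transcript did not pass at 9.755 and 8.525 FPKM, and another DGK5 transcript rose from 6.93 to 10.15 FPKM. Their 24 transcripts had 2 up and 6 down, 8 passing when adjusted over the list alone. Of 12 sterol and sphingolipid genes 3 rose and 7 fell, and of 27 transcripts 6 rose and 8 fell (14 passed when adjusted over the list alone). Squalene synthase SQS1 fell from 99.1 to 44.1 FPKM and LCB1, of sphingoid base synthesis, from 59.3 to 25.2 FPKM, whereas the fatty acid hydroxylase FAH1 rose from 19.2 to 28.8 FPKM, its other transcript not passing at 22.9 and 20.2 FPKM. The median log2 change of each of these 9 lipid lists lay within the central 95% of random lists matched on abundance, from percentile 6.89 for the endoplasmic reticulum list to 85.8 for the desaturases. The endoplasmic reticulum list lay below that range with pseudocounts of 1 and 5, at percentiles 2.49 and 0.5. Some medians changed sign with the most abundant transcript of each gene. The galactolipid and sulfolipid median went from 0.33 to -0.45 (percentile 9.62), and was -0.59 (percentile 3.97) at a minimum of 5 FPKM. Plastid assembly went from 0.15 to -0.22, the desaturases from 0.23 to -0.08 and fatty acid synthesis from 0.05 to -0.02. The other lipid lists had medians below 0 both ways.

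The small heat shock proteins rose together. Of 13 genes 11 rose, 1 fell and 1 did not pass, and the list median log2 change was 1.79 in the authors' deposited table, above every random list. HSP22.0 rose as given above and HSP21, the plastid member, rose to 118 FPKM (log2 change 5.80 in the authors' deposited table), while another HSP21 transcript fell from 34.6 to 16.9 FPKM, HSP15.4 fell from 77.3 to 37.7 FPKM and HSP17.6A did not pass at 6.63 and 8.07 FPKM. All 9 transcripts of HSP21 summed to 83.1 FPKM at 23 °C and 197 FPKM at 43 °C, a log2 ratio of 1.25. Over 35 transcripts 19 rose and 5 fell, and 26 passed when adjusted over the list alone. Among large chaperones, 16 of 24 genes rose and 2 fell. HSP90.1 rose by 3.86 on the log2 scale in the authors' deposited table, and the mitochondrial chaperonin HSP60-3B rose from 42.7 to 186 FPKM. HSC70-1, a cytosolic chaperone expressed without stress, fell from 596 to 156 FPKM, and plastid cpHSC70-1 (172 and 159 FPKM) and the co-chaperone J3 (147 and 143 FPKM) did not pass, though a second J3 transcript rose from 50.3 to 86.5 FPKM. Of 88 transcripts in this list 39 rose and 13 fell (55 passed when adjusted over the list alone), with a median log2 change of 0.37 at percentile 99.9. With the most abundant transcript of each gene the medians were 1.11 for the large chaperones and 3.58 for the small heat shock proteins.

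Endoplasmic reticulum stress genes, which act in the unfolded protein response, rose in 10 of 11 cases. The lumenal chaperone BIP2 rose from 68.5 to 204 FPKM and its partner ERDJ3B from 17.0 to 47.0 FPKM. The exception was CRT3, a calreticulin, at 62.0 and 1.31 FPKM, of which another transcript did not pass at 17.9 and 16.9 FPKM. Their 22 transcripts had 12 up and 4 down (17 passed when adjusted over the list alone), with a median of 0.81 above every random list. Heat shock factors and heat regulators did not rise as a group: 4 of 17 genes rose and 5 fell. MBF1C, a heat-induced coactivator, rose from 25.1 to 70.6 FPKM, HSFB2A fell from 7.35 to 1.46 FPKM and HSFA4C from 16.1 to 7.29 FPKM, and HSFA2 (5.32 and 6.85 FPKM) and HSFA1A (5.28 and 6.19 FPKM) did not pass. Of 47 transcripts 8 rose and 18 fell (26 passed when adjusted over the list alone), the median of -0.42 lying at percentile 0.32. That place rested on transcripts other than the most abundant of each gene, 12 of the lower ones being matched to HSFA2. With the most abundant transcript per gene the median was -0.01. Other HSFA2 transcripts fell from 5.20 to 1.095 FPKM and from 3.95 FPKM to a listed 0. All 17 transcripts of HSFA2 summed to 31.6 FPKM at 23 °C and 12.5 FPKM at 43 °C.

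Nuclear genes of the photosynthetic electron transport chain were mostly lower. Of 35 nuclear genes for light harvesting and photosystems 33 fell and none rose by their most abundant transcripts. PSBS, needed for energy-dependent quenching, fell from 625 to 167 FPKM, and the most abundant LHCB1.3 transcript fell by 2.69 on the log2 scale in the authors' deposited table. A second LHCB1.3 transcript (2912 and 2722 FPKM) and LHCB2.3 (9243 and 8656 FPKM) did not pass. Plastid-encoded photosynthesis transcripts, a group assembled after the values had been seen, went the other way: 17 of 22 rose and 1 fell, with PSAA going from 1.52 to 38.3 FPKM. Their median was only 0.70 FPKM at 23 °C and 3.11 FPKM at 43 °C. More DNA, or more RNA without a poly(A) tail, in the hot libraries stays open for this rise. A minor transcript of PSBY rose from 0.508 to 25.2 FPKM and a minor one of FD2 from 21.0 to 38.8 FPKM. Over 46 transcripts 2 rose and 40 fell (43 passed when adjusted over the list alone), and the median of -0.63 lay at percentile 0.19. Forcing both temperatures to one distribution of values (quantile normalization) brought that median to -0.09, at percentile 28.3, and turned 12 of the lower transcripts higher, among them the most abundant FD2 transcript, which with equal totals no longer passed.

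In the Calvin cycle 13 of 15 genes fell, such as RPE (493 to 168 FPKM) and GAPB (609 to 416 FPKM, and 349 to 85.8 FPKM for a second transcript). The aldolase FBA2 rose from 3720.3 to 4791 FPKM, a second transcript of RCA (Rubisco activase) rose from 267 to 414 FPKM beside a fall of the main one from 1125 to 457 FPKM, and TKL1 did not pass at 535 and 525 FPKM. Of its 22 transcripts 3 rose and 15 fell, 18 passing when adjusted over the list alone, and its median of -0.58, at percentile 2.92, stayed within the central range. Of 24 genes of the C4 cycle 21 fell and 1 rose. PPDK, which regenerates the acceptor of the first carboxylation, fell from 6322 to 1997 FPKM (log2 change -1.67, adjusted p = 3.52e-71 in the authors' deposited table) and the phosphoenolpyruvate transporter PPT1 from 539 to 209.6 FPKM, while PPCK1 did not pass at 138 and 135 FPKM. CA2, a carbonic anhydrase, fell from 234 to 155 FPKM by its main transcript, and a second CA2 transcript rose from 24.4 to 59.8 FPKM. Its 34 transcripts had 6 up and 23 down (30 passed when adjusted over the list alone), with a median of -0.67 at percentile 0.06. In photorespiration 11 of 13 genes fell, among them GGT2 (550.2 to 171 FPKM) and the catalase CAT2 (1042 to 391 FPKM). GLDH3 rose from 265 to 395 FPKM and AGT1 did not pass at 192 and 169.8 FPKM. The photorespiration median was -0.62 (percentile 1.97), with 1 transcript up and 14 down of 21 and 16 passing when adjusted over the list alone.

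Starch and sucrose genes fell in 12 of 20 cases and rose in 5. The starch-degrading enzymes GWD1 (99.4 to 37.3 FPKM) and DPE2 (29.0 to 6.68 FPKM) fell, while the amylase BAM1 rose from 17.3 to 84.2 FPKM and the sucrose synthase SUS1 from 21.5 to 61.0 FPKM. SS2 did not pass at 41.4 and 38.1 FPKM. Over 33 transcripts 8 rose and 17 fell (26 passed when adjusted over the list alone), with a median of -0.60 at percentile 0.09. Among phenylpropanoid and flavonoid genes CHS, the entry enzyme of flavonoid synthesis, fell from 12.1 to 0.0375 FPKM while another CHS transcript rose from 1.58 to 8.075 FPKM. PAL1 fell from 97.1 to 46.7 FPKM, FLS1 rose from 22.8 to 74.6 FPKM, and 4CL3 did not pass at 35.0 and 36.6 FPKM. In all 1 of 8 genes rose and 5 fell, or 3 and 8 of 14 transcripts, 13 passing when adjusted over the list alone, with a median of -0.84 at percentile 0.21. Antioxidant enzymes went both ways: 4 of 14 genes rose and 7 fell, as did 8 and 9 of 30 transcripts, and 18 passed when adjusted over the list alone. The iron superoxide dismutase FSD2 rose from 64.9 to 187 FPKM, and CSD1 from 104 to 157 FPKM and from 55.1 to 143 FPKM by its 2 transcripts. Thylakoid ascorbate peroxidase TAPX fell from 71.8 to 23.498 FPKM, while its other transcript rose from 19.5 to 47.1 FPKM, and the glutathione reductase GR2 fell from 28.6 to 16.9 FPKM, and APX1 did not pass at 204 and 198 FPKM. Of 13 genes of abscisic acid, dehydration and cold response only 2 rose and 3 fell (3 and 4 of 22 transcripts, 7 passing when adjusted over the list alone). The homeobox genes HB7 and HB12 moved apart, from 15.0 to 28.7 FPKM and from 62.7 to 24.1 FPKM, and RD22 (52.7 and 60.1 FPKM) and RD26 (35.9 and 45.1 FPKM) did not pass.

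Markers of leaf cell types moved in several directions. In the epidermal list of wax and cutin genes 6 of 16 genes rose and 4 fell. The fatty acyl reductase CER4 rose from 0.39 to 17.3 FPKM and the cutin hydroxylase CYP86A8 from 17.36 to 51.7 FPKM, CER3 fell from 45.4 to 11.9 FPKM, and DCR (98.8 and 89.8 FPKM) and GPAT4 (74.9 and 79.1 FPKM) did not pass. Of 30 transcripts 14 rose and 6 fell (20 passed when adjusted over the list alone). Their median of 0.38 lay at percentile 99.1, but at -0.0043 with the most abundant transcript of each gene. Vascular genes fell in 7 of 14 cases and rose in 3. SUC2 and SWEET12, which load sucrose into the phloem, fell from 207 to 55.3 FPKM and from 209 to 65.6 FPKM. The secondary wall cellulose synthase CESA4 rose from 6.92 to 13.6 FPKM (another transcript did not pass at 6.12 and 9.27 FPKM), and AHA3 did not pass at 56.0 and 48.9 FPKM. Of 38 transcripts 8 rose and 9 fell, 19 passing when adjusted over the list alone, with a median of -0.06 that became -0.55, at percentile 1.65, with the most abundant transcript of each gene. In the guard cell and stomatal lineage list 5 of 10 genes rose and 1 fell. The lineage receptor TMM was listed at 0 at 23 °C and at 2.43 FPKM at 43 °C, the kinase OST1 rose from 30.9 to 43.6 FPKM while a second OST1 transcript fell from 35.0 to 24.5 FPKM and the sum over its transcripts hardly differed (log2 ratio -0.0049), and FAMA did not pass at 8.77 and 5.59 FPKM. Its 27 transcripts had 8 up and 3 down, with 12 passing when adjusted over the list alone. Of 4 floral genes with a match, 1 rose and 2 fell (2 and 3 of 8 transcripts, 6 when adjusted over the list alone). FT, a flowering signal made in leaves, rose from 5.15 to 9.81 FPKM, SOC1 fell from 46.5 to 26.8 FPKM and, by a second transcript, from 37.0 to 4.64 FPKM, and the petal gene AP3 did not pass at 3.44 and 1.65 FPKM.

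Cell division genes rose in 11 of 15 cases and none fell. The G1 cyclin CYCD3;1 rose from 4.31 to 23.59 FPKM and TSO2, a subunit of ribonucleotide reductase, from 8.02 to 33.0 FPKM. MCM5 (6.61 and 7.80 FPKM) and CDC20.1 did not pass. Of 25 transcripts 16 rose (17 passed when adjusted over the list alone), with a median of 1.18 above 99.99% of random lists. Among clock genes 4 of 13 rose and 6 fell. LHY, a morning regulator, fell from 79.3 to 6.07 FPKM and PRR5 from 155 to 57.5 FPKM, the evening gene TOC1 rose from 10.2 to 20.9 FPKM and FKF1 from 2.41 to 11.5 FPKM, and GI (30.5 and 29.3 FPKM) and ELF3 (11.1 and 11.4 FPKM) did not pass. Of 27 clock transcripts 5 rose and 11 fell (18 passed when adjusted over the list alone). The clock median was -0.51 over these transcripts and -0.07 with the most abundant transcript of each gene. Leaf senescence genes fell in 4 of 6 cases, with NYC1 (58.9 to 27.8 FPKM) and PPH (210.4 to 118 FPKM), both of chlorophyll breakdown, lower, PAO higher (46.7 to 77.0 FPKM) and ORE1 not passing, with 1.03 FPKM at 23 °C. Of these 6 transcripts 5 passed when adjusted over the list alone.

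**Figure D2:**
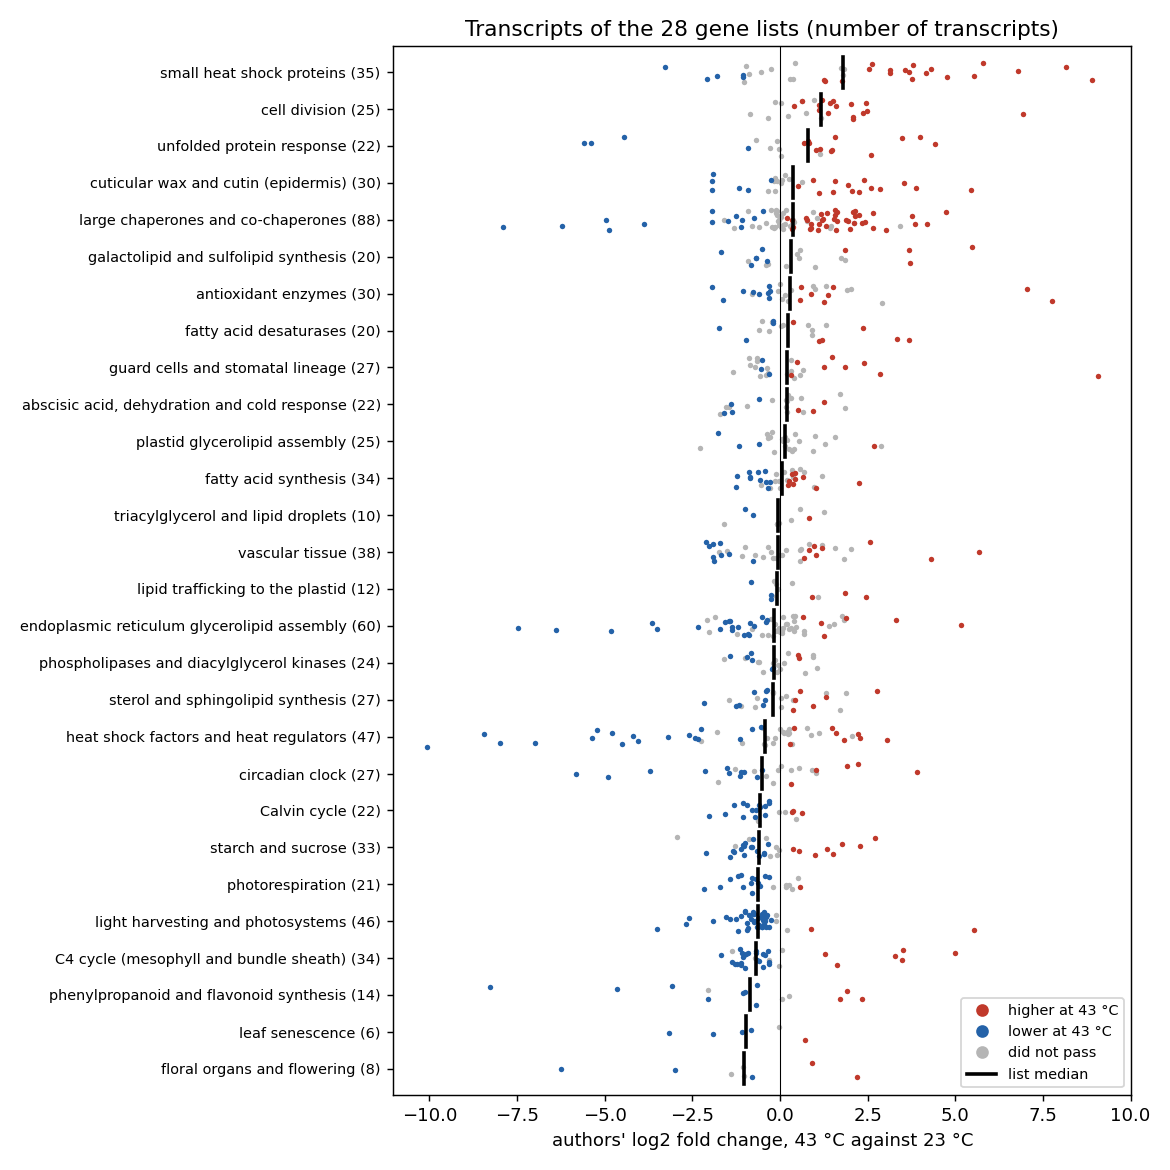
Authors' log2 fold changes (43 °C against 23 °C) of the transcripts of the 28 gene lists, one point per transcript, coloured by the authors' call, with a bar at each list's median and the number of transcripts in brackets. Small heat shock proteins (median 1.79) and cell division (1.18) lie highest, and floral (-1.04), senescence (-0.96) and phenylpropanoid genes (-0.84) lowest.

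Of the 28 lists 5 lay above and 9 below the central 95% of random lists matched on abundance, where 1.4 would lie outside by chance if genes moved independently. Those above were small heat shock proteins, large chaperones, the unfolded protein response, cell division, and wax and cutin. Those below were heat shock factors, nuclear photosystem genes, the C4 cycle, photorespiration, starch and sucrose, phenylpropanoids, the clock, senescence (percentile 1.88) and floral genes (percentile 0.89). Small heat shock proteins, large chaperones, the unfolded protein response, cell division and the C4 cycle kept their side under all 10 alternatives tried. Wax and cutin genes came within the central range in 6 of them, and heat shock factors in 4, among them a minimum of 5 FPKM (percentile 34.5). Phenylpropanoid genes did so in 3, at a minimum of 5 FPKM, summed per gene (percentile 7.31) and by the most abundant transcript, and clock genes in the last 2 of these (percentiles 20.2 and 59.1). Senescence and floral genes came within it at a minimum of 5 FPKM, photosystem genes with quantile normalization, photorespiration genes when summed per gene, and starch and sucrose genes with a pseudocount of 5. Genes of a list do not vary independently, so these places describe the lists and are not tests. Each temperature had its own chamber, and chamber and temperature cannot be told apart.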

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

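The scaling to equal totals, the minimum FPKM of 1, the pseudocount of 1, the most abundant transcript per locus, the E value limit and the omission of transcripts listed at 0 were chosen after seeing the data. No paired analysis was possible because the deposited table gives a single mean per temperature. For that reason the planned edgeR test was not run. Nor were DESeq2, limma, TMM, the replicate block, leaving out single libraries, camera and fry, and per-locus sums have no calls. The counts of higher (9618) and lower (8291) transcripts stayed within 1.5 times of the main ones except under a minimum of 5 FPKM, which left 4447 higher, fewer transcripts being tested. The split moved most with equal totals (68.4% higher) and with the minimum of 5 FPKM (44.5% higher). Changes of at least 2-fold numbered 11970 as deposited, 4024 at the minimum of 5 FPKM, and 6626 and 1856 with pseudocounts of 1 and 5, which shrink changes of rare transcripts by construction. After quantile normalization, which also included a pseudocount of 1, such changes numbered 6472. The 5 lists above the central range numbered 4 or 5 under the 10 alternatives, and the 9 below numbered 5 (minimum of 5 FPKM, fewer transcripts) to 10. Of these 14 lists 5 kept their side in all 10 alternatives: small heat shock proteins, large chaperones, the unfolded protein response, cell division and the C4 cycle. Wax and cutin genes kept it in 4, and their median turned to -0.0043 with the most abundant transcript per locus, and the cause was not tested. Of the named genes, FAD6 (0.041), FAB2 (0.054) and LACS9 (0.0090) changed sign with equal totals, which adds 0.25 to each, and FD2 (0.36) with quantile normalization, which lifts the most abundant transcripts at 43 °C. PIS1 (-0.30) and OST1 (-0.0049) changed sign when all transcripts of the locus were summed, as other transcripts of both fell. Depth is unknown, and for rare transcripts only changes above 1.63 on the log2 scale passed.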

Other observations

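Beyond the lists fixed in advance, 19 groups of genes were assembled after the values had been seen, some of them from genes that had moved most, so their counts describe and do not test. Pathogenesis-related proteins were among the largest falls: PR4 went from 179 to 4.82 FPKM, the osmotin OSM34 from 113 to 3.04 FPKM, and the chitinases EP3 and CHIA from 159 to 4.55 FPKM and from 78.9 to 2.80 FPKM. Of the 9 genes gathered 7 fell and 2 rose, CHI-B, which was listed at 0 at 23 °C, and the ribonuclease RNS1, which went from 39.0 to 72.0 FPKM. Of 14 genes of salicylate and immune signalling 13 fell, among them PAD4 (33.1 to 3.15 FPKM), the transcription factors WRKY33 (43.8 to 1.94 FPKM) and WRKY70 (26.49 to 3.94 FPKM), SARD1 (10.1 to 0.563 FPKM) and the receptor kinase SOBIR1 (21.9 to 3.50 FPKM), while RBOHD rose from 31.9 to 43.7 FPKM.

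Beside NMT2, other genes for the synthesis of glycine betaine, a solute that salt-tolerant plants accumulate, and of the methyl cycle that feeds it were mostly lower. Of the 9 matched genes other than NMT2, 8 fell and MTHFR1 rose. Choline monooxygenase went from 1226 to 466 FPKM, an S-adenosylmethionine synthetase (AT3G17390) from 3040.2 to 659 FPKM, methionine synthase from 1223 to 501 FPKM, the folate reductase MTHFR2 from 469 to 141 FPKM and SAHH1 from 1189 to 726 FPKM. Of 12 genes of salt and ion transport, 7 rose and 4 fell by their most abundant transcripts, with a median log2 change of 0.39. Over all 60 transcripts 14 rose and 25 fell, with a median of -0.56 in the authors' deposited table, below every random list. The sodium exporter SOS1 held 28 of the 60 transcripts and 18 of the 25 lower ones, so that place rests largely on 1 gene. SOS1 fell from 182 to 45.8 FPKM, with none of its transcripts higher, and the sodium transporter HKT1 from 81.5 to 24.7 FPKM. The vacuolar exchanger NHX2 rose from 23.4 to 41.6 FPKM by its most abundant transcript and did not pass by another (21.4 and 22.9 FPKM).

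All tests in the following paragraphs were chosen only after the result was seen. Transcripts matched to organelle genomes were higher at 43 °C. Of 55 plastid-encoded transcripts 39 rose and 1 fell, and of 32 mitochondrion-encoded transcripts with named proteins 31 rose; PSBA went from 3.77 to 61.8 FPKM and COX2 from 2.18 to 55.5 FPKM, against the fall of nuclear photosystem genes. Their medians were 3.10 and 5.74 on the log2 scale in the authors' deposited table, and 1.28 and 2.37 with quantile normalization. That setting includes a pseudocount of 1, which by itself shrinks changes of transcripts this rare (median 0.46 and 0.17 FPKM at 23 °C). Equal totals would raise the deposited medians further, to 3.35 and 5.99, so that scaling could not have removed the rise and was no test of it. The deposited medians exceed 0.25, so a constant shift of that size, in either direction, does not account for them. More DNA, or more RNA without a poly(A) tail, in the hot libraries stays open: nuclear transposon-like transcripts, which it could also raise, had a median of 0.53, at percentile 99.5 of abundance-matched lists (0.23 by their most abundant transcripts). An effect of temperature on organelle RNA may equally account for the rise and was not separately tested.

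Some meristem genes rose beside those of cell division: of 10 genes of meristems and young leaves 5 rose, 2 fell and 3 did not pass. STM, a regulator of shoot meristems, went from 0.0375 to 4.67 FPKM and KNAT6 from 0.04 to 1.36 FPKM, while the meristem receptor CLV1 fell from 15.3 to 9.70 FPKM. ANT did not pass at 3.01 and 4.24 FPKM, though a second ANT transcript rose from 1.70 to 3.06 FPKM. More vein or stem tissue in the hot samples was not predicted to lower phloem genes, which had a median of -1.78 by their most abundant transcripts, with 5 of 6 lower, and -0.37, at percentile 10.9, over all 16 transcripts. Xylem genes disagreed, with a median of 0.58 at percentile 98.7, 13 of 32 transcripts higher and 4 lower, so more tissue rich in xylem is not excluded. A larger share of young tissue stays open: cytosolic ribosomal protein transcripts, not used to find the pattern, had a median of 0.24, at percentile 99.96 of matched lists, whereas 7 genes with roles in young leaf growth, CLV1 counted among them, had 2 higher and 2 lower, with a median at percentile 93.3, within the central range. Faster division at 43 °C within leaves of the same age may give the same values, and leaf age is not given in the sources used here.

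Among clock genes sorted by phase after their values had been seen, all 7 matched morning-phased ones fell and 4 of 7 evening-phased ones rose, and PRR5, placed in neither set, fell from 155 to 57.5 FPKM. The median of the evening set exceeded that of the morning set by 1.93 on the log2 scale, which restates the pattern and tests no explanation. The hour of harvest is not given in the sources used here, so a different phase at harvest and an effect of temperature on the clock genes cannot be told apart. GI, an evening gene, did not pass at 30.5 and 29.3 FPKM.

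The most abundant transcript of the table at 23 °C had no Arabidopsis match and fell from 14897 to 4847 FPKM. Cytosolic ribosomal protein transcripts rose in 38 and fell in 10 of 78 cases, and histone transcripts rose in 31 and fell in 8 of 61.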
